A study of Nitraria sibirica with 9 samples.

How the data were processed

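RNA from leaves of Nitraria sibirica, a shrub of saline soils, was sequenced in 9 libraries. Seedlings grown in a greenhouse received no added NaCl, 100 mM or 400 mM for 3 days, and each level has 3 replicates. Per the labels, salt was raised stepwise each day and started so that the levels were reached together. The labels number the replicates but do not say whether they came from separate plants. The p-values therefore measure only the spread between these samples, which may be technical.

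The features are named clusters in the deposited files, and the series title describes a transcriptome assembled without a genome. Each library was deposited as a table of 126059 clusters with 2 values, a read count and an FPKM. The deposited read counts are estimated counts, as between 38.5% and 42.5% of clusters in a library hold a count that is not whole. The deposited FPKM values (fragments scaled to cluster length and library size) were computed by the authors, per the file headers. The length they imply is about 241 to 251 bases shorter than the deposited cluster length. A further deposited table of the whole series held the FPKM of 31628 clusters with their lengths, from 201 to 15080 bases with a median of 1476. These are exactly the clusters with an FPKM over 0.3 in all 9 libraries, and 0 of the FPKM values differed from the library tables. Bowtie2 2.0.6 and TopHat2 2.0.9 are named in the submitters' processing notes, with no role stated. The assembler, the counting tool and any annotation are not given in the sources used here. The strand setting of the counting is likewise not given in the sources used here.

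The files used here do not pair cluster names with gene names, protein descriptions or terms, and no reference genome was used. The 39 gene lists fixed before the data were examined, the tests of those lists and the enrichment of terms were therefore not run. Clusters are described by abundance, by their course over the salt levels and by presence or absence. Clusters were to be named by a rule fixed before the data were examined. It took, per comparison, those with an adjusted p under 0.05, a mean of at least 5 CPM (counts scaled to library size) in the higher group and no overlap between the libraries compared, ranked by fitted fold change. Its condition on protein descriptions could not be applied. Because the clusters carry no gene name, only the 2 largest rises and the 2 largest falls are named. In 100 mM against 0 mM, 222 higher and 28 lower clusters met the conditions, and the other comparisons gave none.

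Counts were rounded to whole numbers. Total counts ran from 16502576 to 23932857 per library. Of the 126059 clusters, 4587 had no count in any library and 44398 had a count in every library. No pair of libraries held identical counts. Clusters that share the number 23439 before the point made up 98635 of the names (78.2%). Members of gene families, alleles and fragments of 1 gene may lie in different clusters, and reads shared between near-identical clusters could be divided among them by the counting. Single clusters are therefore uncertain as genes.

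The main test was the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with the package's default fit, TMM normalization and the default filterByExpr filter, which left 56832 clusters. All 9 libraries entered 1 fit with salt level as 3 groups and no further term, and 6 residual degrees of freedom. Calls required a Benjamini-Hochberg adjusted p under 0.05. The common biological coefficient of variation was 0.758 and the median over clusters 0.567. For the clusters named below, fold changes where a group had 0 counts were computed against a floor of 3 counts over the group. They are lower bounds that cover counting error only. Medians over clusters and plotted fold changes are fitted values. CPM of clusters and floors in CPM use the counts of the clusters tested, scaled by the TMM factors, while presence patterns and values at equal depth use library totals with no such factor.

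To compare libraries at equal depth, each was thinned at random to 16502576 counts, the total of the shallowest, and numbers of clusters with a count were averaged over 10 draws. Clusters tested were sorted by mean CPM over all 9 libraries into 4 classes, under 1, 1 to 10, 10 to 100 and over 100 CPM. In 1 thinned draw, log2(CPM + 0.5) of each cluster was set against its mean over all libraries. Such single values were compared by exact two-sided permutation tests, which cannot go below p = 0.1 with 3 libraries against 3. Overlap between both salt comparisons, which share the 0 mM libraries, was set beside 20 simulations of unchanged groups and beside the overlap of independent lists. In the same simulations the 241 higher and 43 lower clusters with the smallest p at 100 mM were followed at 400 mM. This gives what selection and shared libraries produce with no change. The clusters were taken by rank and not matched to the called ones in abundance or spread.

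The fit was tested on 3 simulated data sets drawn from the means, library sizes and spread of these libraries, with 200 clusters changed in each. In the data 8768 clusters differed at 100 mM at an unadjusted p under 0.05, so the adjustment may be stricter in these simulations. The shares called below may therefore not hold for the data. For 100 mM against 0 mM, with a mean of 52332 clusters tested, it called 34.5% of clusters changed 16-fold, 18.7% of those changed 8-fold, 0.741% of those changed 4-fold and 0% of those changed 2-fold. Among clusters of at least 5 CPM the 16-fold and 8-fold shares were 66.7% and 41.2%. For 400 mM against 0 mM it called 31.9% of those changed 16-fold and 16.3% of those changed 8-fold. False calls averaged 0.667 per simulation in either comparison. With DESeq2 they averaged 261 for 100 mM against 0 mM and 250 for 400 mM against 0 mM. In the same order they averaged 8 and 9.33 with edgeR's newer adjusted deviances, and 0.667 and 0 with limma-voom.

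Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, library size alone, no filter and a filter of at least 1 CPM in 3 libraries, DESeq2 1.42.0, limma 3.58.1 on log2(FPKM + 1) and log2(FPKM + 0.1) for clusters with an FPKM of at least 0.3 in 3 libraries, a fit of only the groups compared, the replicate number as a block, glmTreat against a log2 fold change of 1, and each library left out in turn. Added after seeing the data were a contrast of both salt levels together against 0 mM, edgeR's newer adjusted deviances, limma-voom, the series table's clusters alone and a fit without replicate 1 of either salt level. The design fixed beforehand names edgeR's test but not the form of its deviances, and the package default was kept as the main fit after the counts of both forms had been seen. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for tables and plots.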

Results

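Leaf transcriptomes of Nitraria sibirica, a salt-tolerant shrub, were compared after 3 days at 0, 100 and 400 mM NaCl. The series asks how the leaf transcriptome differs between plants without added salt and plants at a moderate or a high salt level. Each level had 3 libraries, and expression was counted over clusters from a transcriptome assembled without a genome. Total counts averaged 18195163 ± 1466782 at 0 mM, 20109342 ± 2232369 at 100 mM and 22782439 ± 1070807 at 400 mM (SD, n = 3 each). The 0 mM libraries 1, 2 and 3 held 16502576, 19094481 and 18988432 counts. The 100 mM libraries held 22494402, 19763620 and 18070003 counts, and the 400 mM libraries 22599699, 21814761 and 23932857, in the same order. The clusters carry no gene names or descriptions in the files used here, so that groups of clusters are described in place of pathways.

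At 100 mM, 284 of 56832 clusters changed against 0 mM, 241 of them upward and 43 downward. The clusters that rose were mostly well expressed, with a median of 49.1 CPM, whereas those that fell had a median of 7.36 CPM. The median rise was 5.57-fold, a log2 fold change of 2.48. The median fall was 9.92-fold, a log2 fold change of -3.31. By abundance, 75 clusters over 100 CPM rose and 1 fell, and between 10 and 100 CPM 124 rose and 18 fell. Between 1 and 10 CPM 41 rose and 18 fell, and under 1 CPM 1 rose and 6 fell. Of the 241 clusters that rose, 20 had no count in any 0 mM library, and 17 of the 43 that fell had none in any 100 mM library. Only 1 of the 43 had no count in any 400 mM library, so most of these 17 were absent at 100 mM alone. Fitted folds of the 20 and the 17 depend on the fit. Without them, the median rise of the other 221 was 5.18-fold (log2 2.37) and the median fall of the other 26 was 5.34-fold (log2 -2.42). All 241 and all 43 had 100 mM libraries that did not overlap the 0 mM libraries. Over all clusters tested, 25.5% had no overlap, against 10% by chance. At an unadjusted p under 0.05, 8768 clusters differed, 5056 higher and 3712 lower.

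These calls were made with edgeR's quasi-likelihood test and rest on all 9 libraries. Without 400 mM replicate 1 the count was 649 and without 400 mM replicate 3 it was 172, while leaving out any other library gave between 0 and 7 calls. Other tools gave 6187 calls (DESeq2, 3769 higher and 2418 lower), 188 (limma-voom, 170 and 18), 1702 (limma on log2(FPKM + 1), 762 and 940) and 1177 (limma on log2(FPKM + 0.1), 637 and 540). The share of rises was 84.9% with edgeR, 44.8% with limma on log2(FPKM + 1) and 54.1% on log2(FPKM + 0.1), where test, scaling and filter all differ from edgeR's. With library size as the only scaling, the median log2 fold change of all clusters moved by -0.25, and 138 clusters were called, 105 higher and 33 lower. The unadjusted counts then turned to 3234 higher and 6299 lower.

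Some clusters went from no count at 1 level to a mean of at least 5 CPM at another, in part with a wide spread between libraries. Cluster-23439.82864 had 0 counts in all 3 libraries at 0 mM and 31.1 CPM ± 25.9 at 100 mM (SD, n = 3), at least 620-fold higher. Its adjusted p by edgeR's quasi-likelihood test was 0.0499, and it stood at 52.5 CPM ± 37.9 at 400 mM. Cluster-23439.45778 likewise had 0 counts at 0 mM, with 15.4 CPM ± 11.2 at 100 mM (at least 306-fold higher, edgeR adjusted p = 0.0417) and 20.3 CPM ± 11.2 at 400 mM. Cluster-23439.61384 went the other way. It was at 31.0 CPM ± 4.06 at 0 mM and had 0 counts in all 6 salt libraries, which makes it at least 578-fold lower at 100 mM (edgeR adjusted p = 0.0339) and at least 679-fold lower at 400 mM (edgeR adjusted p = 0.0942). Cluster-23439.48309 stood at 25.5 CPM ± 11.9 at 0 mM and had 0 counts in the 3 libraries at 100 mM, at least 476-fold lower (edgeR adjusted p = 0.0387). At 400 mM it was again at 20.1 CPM ± 13.2, and its difference between both salt levels did not pass the test (edgeR adjusted p = 0.269). None of these 4 clusters is in the table with lengths, as that table holds only clusters with an FPKM over 0.3 in all 9 libraries. All 4 lost their call when any 0 mM or 100 mM library was left out. Such on and off patterns also occurred between libraries of 1 salt level, as 732 clusters had at least 1 CPM in a single library and no count in the other 8.

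At 400 mM, no cluster passed the test against 0 mM, although 7406 clusters differed at an unadjusted p under 0.05, 4620 of them higher and 2786 lower. Adjustment is made within each comparison, so a p-value that passed at 100 mM could fail at 400 mM. Cluster-23439.61384, for example, was called at 100 mM at an unadjusted edgeR p of 1.07e-05 but not at 400 mM at 9.95e-06. The clusters called at 100 mM were followed at 400 mM against the same 0 mM libraries, so part of any agreement comes from those shared libraries. Of the 241 that rose at 100 mM, 238 had a higher fitted level at 400 mM than at 0 mM, with a median of 3.22-fold (log2 1.69), and 231 had an unadjusted p under 0.05. Of the 43 that fell at 100 mM, 39 were lower at 400 mM, with a median log2 fold change of -0.96, and 25 had an unadjusted p under 0.05. In 20 simulations with no change, clusters selected in the same numbers by their p at 100 mM gave means of 229 of 241 (range 224 to 235) and 37.1 of 43 (range 33 to 40) in the same direction. The selected rises had a simulated median log2 fold change of 2.14 at 400 mM (range 1.78 to 2.48) and the falls -0.99 (range -1.51 to -0.56). With an unadjusted p under 0.05 the simulations gave a mean of 148 for the rises (range 131 to 164) and 15.3 for the falls (range 11 to 21). For the rises, the 238 in the same direction lay above the simulated range and the median of 1.69 below it. For the falls, the 39 in the same direction and the median of -0.96 lay within the simulated ranges. The 231 and 25 clusters at an unadjusted p under 0.05 lay above their simulated ranges. The simulated clusters were taken by rank of p and not matched to the called ones in abundance or spread. Their median log2 fold change at 100 mM was 3.34 for the rises and -4.26 for the falls, beside 2.48 and -3.31. The medians and the counts at an unadjusted p under 0.05 are therefore not compared on equal terms. The share of clusters with no overlap between the groups was 22.8%, against 10% by chance.

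The count of 0 came from edgeR's quasi-likelihood test and differed by tool and by library. DESeq2 called 4606 clusters (2988 higher, 1618 lower), limma on log2(FPKM + 1) 208 (94 higher, 114 lower), edgeR with the newer adjusted deviances 35 and limma-voom 1. Without 400 mM replicate 1, edgeR called 120 clusters, 109 higher and 11 lower, and without 100 mM replicate 2 it called 1. With the replicate number as a block it called 83, 82 higher and 1 lower. Without replicate 1 of either salt level, a fit added after seeing the data, it called 440, 391 higher and 49 lower. With library size as the only scaling the unadjusted counts turned to 3160 higher and 4412 lower, with the median of all clusters moved by -0.19.

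**Figure D1:**
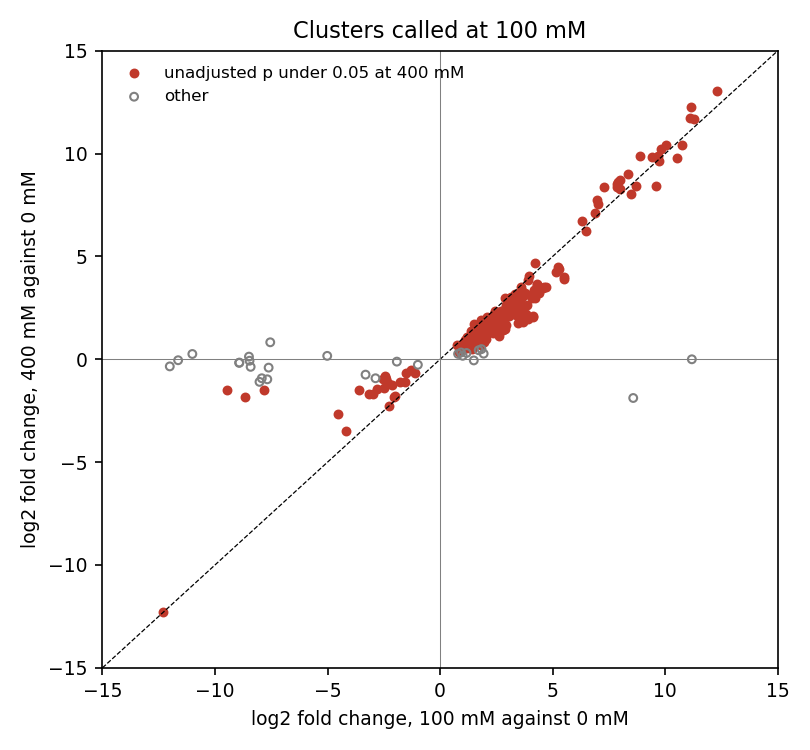
Each point is 1 of the 284 clusters called at 100 mM, with its log2 fold change at 100 mM on the horizontal axis and at 400 mM on the vertical axis, both against 0 mM; filled points have an unadjusted p under 0.05 at 400 mM, and the dashed line marks equal values. The 241 clusters that rose have medians of 2.48 and 1.69, but both axes use the same 0 mM libraries and the clusters were selected on the horizontal one, which in simulations with no change gave 3.34 and 2.14; the fitted values far from 0 belong to clusters with 0 or few counts in 1 group and are not bounds.

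Between 400 and 100 mM no cluster passed edgeR's quasi-likelihood test. Salt was raised stepwise so that both levels were reached together, so this comparison may join salt level with time in salt. At an unadjusted p under 0.05, 3992 clusters differed, 2065 higher at 400 mM and 1927 lower. Among the 241 clusters that rose at 100 mM, 94 were lower at 400 mM than at 100 mM and 0 were higher, at an unadjusted p under 0.05. Among the 43 that fell, 37 were higher again at 400 mM and 0 were lower. These clusters were chosen for their change at 100 mM, and both comparisons use the 100 mM libraries. Clusters selected in the same way in the simulations with no change gave means of 56.1 (range 40 to 67) and 32.5 (range 28 to 37). They were not matched to the called clusters in abundance or spread, so this comparison is only a rough guide. The share with no overlap was 14.4%, against 10% by chance. DESeq2 called 1363 clusters (664 higher, 699 lower), limma on log2(FPKM + 1) 11, edgeR with the newer adjusted deviances 1 and limma-voom 0.

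With both salt levels joined against 0 mM, a contrast added after seeing the data, 84 clusters changed by edgeR's quasi-likelihood test, 67 upward and 17 downward. All 67 and 14 of the 17 were also called at 100 mM. The 67 had a median log2 fold change of 2.78 at 100 mM and 2.24 at 400 mM, and the 17 had medians of -3.88 and -1.78. No cluster was called at both levels in the main edgeR test, which follows from its 0 calls at 400 mM, while edgeR with the newer adjusted deviances called 33 and DESeq2 2520. At an unadjusted p under 0.05, 3005 clusters were higher at both levels and 1074 lower at both, while 23 went opposite ways. Unchanged groups simulated against the same controls gave means of 452 and 174. Their lists averaged only 2422 clusters at 400 mM and 2429 at 100 mM, beside 7406 and 8768 observed. Independent lists gave 411 and 182 at the observed sizes, but 27.97 and 28.33 at the simulated sizes. Shared controls alone thus raised the simulated overlap far above that of independent lists. As the list sizes differ, 3005 and 1074 cannot be set directly beside 452 and 174. Fold changes at both levels correlated across clusters, which are not independent replicates, at r = 0.63, beside 0.50 in the simulations. The covariance was 1.52 beside 0.635 simulated, a difference of 0.884. With 3 control libraries the controls could not be split so that each comparison kept at least 2 of its own. The exact part of the agreement that comes from the shared controls therefore stays open. In the 20 simulations with no change, the correlation ranged from 0.484 to 0.516 and the covariance from 0.603 to 0.666. The observed values lay above both ranges. Shared controls alone, with the simulated spread, thus did not give all of the agreement between both levels. The 84 calls became 847 without 400 mM replicate 1 and 0 to 6 without any other library. They became 6919 with DESeq2 (4086 higher, 2833 lower), 1608 with edgeR's newer adjusted deviances (898 and 710), 25 with DESeq2 size factors in edgeR and 0 with glmTreat. The direction turned with limma on log2(FPKM + 1), at 844 higher and 1736 lower, and on log2(FPKM + 0.1), at 656 and 723. With library size as the only scaling 49 clusters were called higher and 20 lower, while the unadjusted counts turned from 5220 higher and 4210 lower to 3376 and 7185, with the median of all clusters moved by -0.22.

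Fold changes between salt and 0 mM differed by abundance class, with lower values for scarce than for abundant clusters. The classes were set by the mean over all 9 libraries, which include the salt libraries. A cluster's own change thus helps to place it, and part of the difference between classes may come from that sorting. In the edgeR fit the median log2 fold change at 100 mM was -0.37 for the 16784 clusters under 1 CPM, -0.11 for 25915 between 1 and 10 CPM, 0.13 for 12443 between 10 and 100 CPM and 0.26 for 1690 over 100 CPM. At 400 mM the same medians were -0.23, -0.07, 0.13 and 0.24. With library size as the only scaling at equal depth, the 4 medians were -0.31, -0.30, -0.12 and 0.00 at 100 mM and -0.22, -0.20, -0.06 and 0.04 at 400 mM. The sign for 10 to 100 CPM thus depended on the scaling and the median over 100 CPM came close to 0, while the lowest class stayed under the highest with either scaling. Per library, the mean log2 deviation of clusters over 100 CPM minus that of clusters under 1 CPM was -0.32 ± 0.14 at 0 mM, 0.22 ± 0.14 at 100 mM and 0.09 ± 0.09 at 400 mM (SD, n = 3). The salt levels exceeded 0 mM by 0.54 and 0.41, each with an exact two-sided permutation p of 0.1, the smallest that 3 libraries against 3 allow. Between both salt levels the difference was -0.13 (exact p = 0.3). Clusters under 1 CPM held 1.29% ± 0.0631 of the counts at 0 mM, 0.867% ± 0.146 at 100 mM and 0.965% ± 0.0671 at 400 mM.

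**Figure D2:**
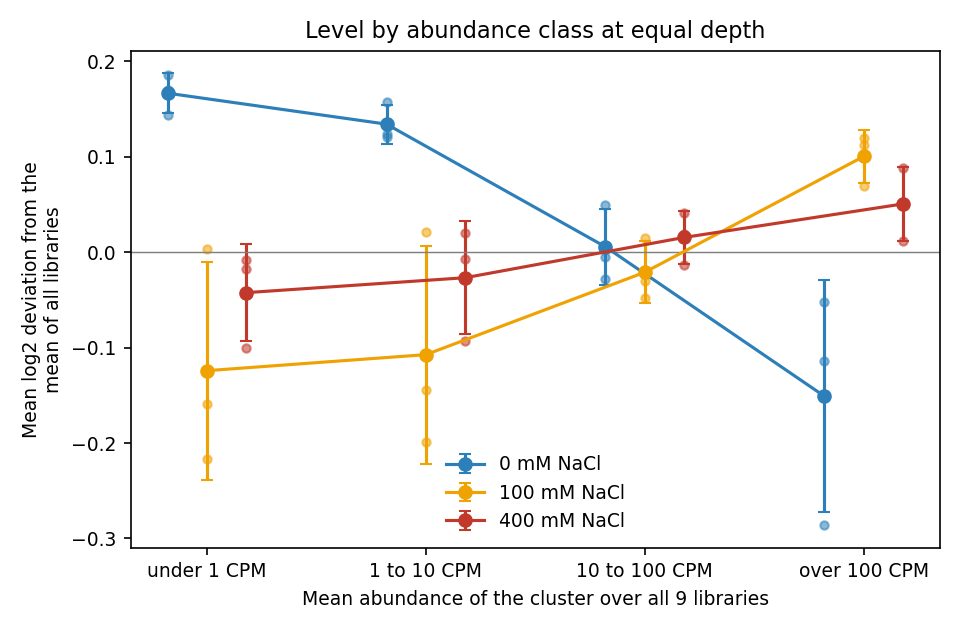
The horizontal axis gives 4 classes of clusters by mean CPM over all 9 libraries, and the vertical axis the mean log2 deviation of a class from the mean of all libraries at equal depth; small points are libraries, large points and bars are the mean and SD of 3 libraries at 0, 100 and 400 mM NaCl. Under 1 CPM the 0 mM libraries lie highest, with a mean of 0.17, and over 100 CPM they lie lowest, with a mean of -0.15.

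At equal depth, fewer clusters were detected in each salt library than in any 0 mM library, which did not hold at full depth. At equal depth 89337 clusters ± 535 had a count at 0 mM, 80387 ± 5513 at 100 mM and 83643 ± 2489 at 400 mM (SD, n = 3). The exact two-sided permutation p was 0.1 for either salt level, the smallest possible. Both salt levels overlapped (exact p = 0.4). At full depth the 0 mM, 100 mM and 400 mM means were 90214, 82248 and 86850 clusters, and the groups overlapped, since 100 mM replicate 1 (89744) and 400 mM replicate 1 (89256) exceeded 0 mM replicate 1 (89000). The most abundant cluster took 2.88%, 2.70% and 2.56% of the counts and the 100 most abundant 19.4%, 18.2% and 17.9%. The whole class over 100 CPM went the other way. It held 49.3% ± 0.779 of the counts of clusters tested at 0 mM, 52.5% ± 1.65 at 100 mM and 51.2% ± 1.41 at 400 mM. The exact two-sided permutation p against 0 mM was 0.1 at 100 mM and 0.2 at 400 mM.

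**Figure D3:**
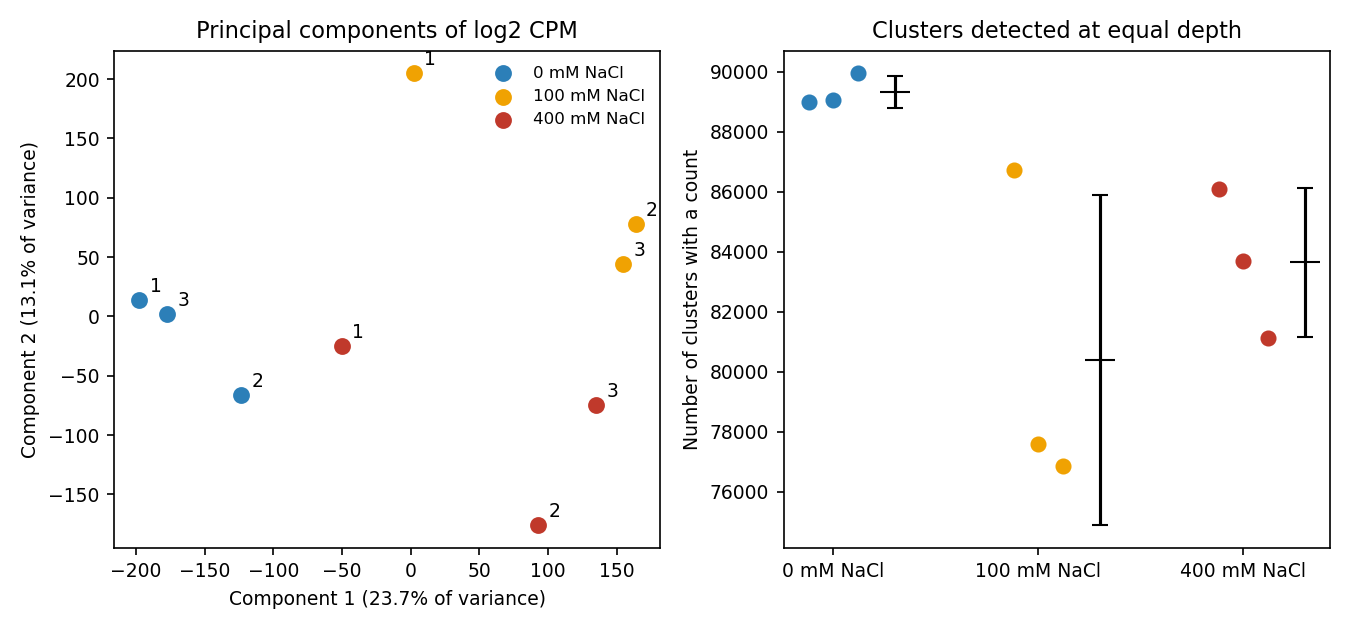
The left panel shows the 9 libraries on the first and second principal components of log2 CPM, which hold 23.7% and 13.1% of the variance, with the replicate number beside each point; the right panel shows the number of clusters with a count at equal depth per library, with the mean and SD of 3 libraries. The 0 mM libraries lie at -198 to -124 on the first component and at 89000 to 89955 clusters, above all salt libraries.

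On average over pairs, libraries at 100 and 400 mM correlated more with each other than with 0 mM. An exception was 400 mM replicate 1, at 0.786, 0.822 and 0.794 with the 0 mM libraries and 0.809, 0.792 and 0.796 with the 100 mM libraries. The mean Pearson correlation of log2 CPM across clusters was 0.803, 0.816 and 0.812 within 0, 100 and 400 mM. Between 100 and 400 mM it was 0.808 ± 0.0185, between 0 and 100 mM 0.762 ± 0.0181 and between 0 and 400 mM 0.773 ± 0.0277 (SD over 9 pairs of libraries, which share members). On the first principal component the 0 mM libraries lay at -198, -124 and -177. The 100 mM libraries lay at 2.16, 164 and 155, and the 400 mM libraries at -50.0, 92.6 and 135, so that replicate 1 of either salt level lay nearest to the controls. Mean correlations with the 0 mM libraries were 0.776, 0.751 and 0.759 for 100 mM replicates 1 to 3 and 0.800, 0.761 and 0.756 for 400 mM replicates 1 to 3.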

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

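The newer adjusted deviances, limma-voom, the fit without replicate 1 of either salt level, the series table's clusters alone and the contrast of both salt levels together were chosen after seeing the data. Counts below are calls for 400 mM against 0 mM, 100 mM against 0 mM, 400 mM against 100 mM, both salt levels together against 0 mM, and the overlap of both salt levels, which were 0, 284, 0, 84 and 0 with edgeR's quasi-likelihood test. DESeq2 gave 4606, 6187, 1363, 6919 and 2520. Limma on log2(FPKM + 1) gave 208, 1702, 11, 2580 and 175, and on log2(FPKM + 0.1) 194, 1177, 22, 1379 and 152. For the overlap, these limma settings were not among the alternatives fixed beforehand. The other scalings, the filters, glmTreat and the fit of only the groups compared were not either. The newer adjusted deviances gave 35, 1103, 1, 1608 and 33. The fit without replicate 1 of either salt level gave 440, 920, 1, 1606 and 377, and the series table's clusters alone 8, 1460, 0, 1565 and 8. That table holds only clusters over 0.3 FPKM in all 9 libraries, so it leaves out clusters that were off in any library. Limma-voom gave 1, 188, 0, 71 and 1. Library size alone gave 138 at 100 mM, the filter at 1 CPM 487 and glmTreat 1. DESeq2 size factors in edgeR gave 25 for both levels together, and glmTreat 0. Except where construction shows it, the cause was not tested. Beyond these, the counts stayed within 1.5 times under the other scalings and filters and the fit of only the groups compared.

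With each library left out in turn, calls ranged from 0 to 120 for 400 mM against 0 mM, 0 to 649 for 100 mM against 0 mM, 0 to 0 for 400 mM against 100 mM, 0 to 847 for both levels together and 0 to 105 for the overlap. Except for 400 mM against 100 mM, the highest value came without 400 mM replicate 1. At 100 mM, leaving out 0 mM replicates 1, 2 and 3 gave 0, 0 and 1 calls, 100 mM replicates 7, 2 and 1, and 400 mM replicates 2 and 3 gave 2 and 172. The share of rises at 100 mM was 84.9% with edgeR, 60.9% with DESeq2, 44.8% on log2(FPKM + 1) with 762 higher and 940 lower, and 54.1% on log2(FPKM + 0.1). For both levels together it was 79.8% with edgeR and 32.7% on log2(FPKM + 1). DESeq2 called all 284 clusters called by edgeR, and limma on log2(FPKM + 1) called 251 of them.

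With the replicate number as a block, calls were 83, 601, 0, 567 and 83 in the same order. Labels tie no replicate number to a shared plant or batch, and only 1 of 9 same-numbered pairs had a correlation of deviations over 0.1 (range -0.009 to 0.172). Of the 9 libraries, 6 correlated best with a library of their own number, a hint from the data and not from the design. Of 22 alternatives, the 4 named clusters kept their call in 10 (Cluster-23439.82864), 11 (Cluster-23439.45778), 13 (Cluster-23439.61384) and 13 (Cluster-23439.48309), and 0 reversed. Their adjusted p ranged up to 0.397, 0.265, 0.126 and 0.226. The gap between mean correlations within and between salt levels was 0.0297 on log2 CPM and 0.0246 on log2(FPKM + 1). The alternatives fixed beforehand for gene lists and enriched terms were not run. In simulated data of this depth and spread, 8-fold changes were called in 18.7% of clusters at 100 mM and 16.3% at 400 mM, so a missing call is no evidence of an unchanged cluster.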

Other observations

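Presence and absence were compared over all 9 libraries. Of 31466 clusters that were in each library either at 0 counts or at 1 CPM or more, 23073 were present in all 9 libraries and 3806 were absent from 1 to 8 of them. Of those 3806, 46 had a pattern that follows salt level (1.21%), and since 6 of the 510 possible patterns do so (1.18%), a small share is given by construction. Clusters absent from exactly the 0 mM libraries numbered 18, exactly the 100 mM libraries 11 and exactly the 400 mM libraries 0. Clusters present in exactly the 0, 100 and 400 mM libraries numbered 7, 7 and 3. The other 81 sets of 3 libraries had a median of 3 for either kind, with ranges of 0 to 18 absent and 0 to 11 present. The salt groups averaged 9.67 absent and 5.67 present, against 4.16 and 3.35 over the other sets, or 2.32 and 1.69 times as many. Another 947 clusters were absent from 1 library alone and 732 were present in 1 alone. The patterns were thus not filled evenly, and the 1.18% is no sound yardstick for the 1.21%.

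Chosen only after the result was seen were the tests on depth, on 400 mM replicate 1, on the depth of the 400 mM libraries and on other splits of the libraries. The depth test was reworded to the difference between 400 and 0 mM after its first form left the question open. How the spread test and the test on the share of patterns were read was also set after their values were seen.

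For clusters absent from exactly 3 libraries, salt level and a variation of presence between libraries unrelated to salt were weighed. The 3 salt groups had 2.32 times as many such clusters as the mean of the other sets, but 1 of the other sets reached 18, as many as the 0 mM set, and the 400 mM set had 0. An effect of salt on this kind of pattern therefore stays open. Of the partly absent clusters 98.8% had patterns that do not follow salt level, but an even spread over the possible patterns gives that share as well. The patterns were not evenly filled either, as 947 clusters were absent from 1 library alone and 732 present in 1 alone. This test therefore decides nothing for or against salt.

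At equal depth fewer clusters were detected in the salt libraries. Depth is removed from that comparison by construction, and a few abundant clusters do not account for it. The 400 mM libraries were each deeper than every 0 mM library, and at equal depth their mean differed from 0 mM by -5694 clusters, over 2 SD of either group. The difference of -8950 at 100 mM was under 2 SD of its own group (SD 5513). Without the 100 most abundant clusters the difference between 100 and 0 mM was -9084, beside -8950 with them, and the groups stayed apart. The 100 most abundant clusters of a library held a smaller mean share at 100 mM (18.2%) and 400 mM (17.9%) than at 0 mM (19.4%). Their removal was therefore a weak test. It also did not test the whole class over 100 CPM, which held a larger mean share at 100 mM (52.5%) and 400 mM (51.2%) than at 0 mM (49.3%). Salt level, RNA quality and the mix of leaf cell types stay open as explanations, since no marker genes could be identified by name here.

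Adjustment is made within each comparison, so 284 against 0 calls is not by itself a measure of a difference between the levels. By edgeR's quasi-likelihood test, Cluster-23439.61384 had an unadjusted p of 9.95e-06 at 400 mM (adjusted p = 0.0942). At 100 mM it had 1.07e-05 (adjusted p = 0.0339), so a like p-value passed at 100 mM and failed at 400 mM. Calls at 100 mM but none at 400 mM were weighed against 3 technical explanations. Depth argues the other way, as the 400 mM libraries held on average 1.13 times as many counts as those at 100 mM. Of the 6 salt libraries, 400 mM replicate 1 had the highest correlation with the controls. Without it there were 120 calls at 400 mM, and 0 without replicate 2 or replicate 3, so that library may hold down the count. The same removal raised the calls for 100 mM against 0 mM, which does not compare that library, from 284 to 649. The rise was thus not particular to 400 mM, and the gap between the levels stayed. A larger spread at 400 mM stays open: the median within-group SD was 1.01 times that at 100 mM over all clusters, under the bound set beforehand to speak against it, but 1.06 times over 10 CPM, where 218 of the 284 called clusters (76.8%) lie. A weaker response at 400 mM stays open too. Of the 241 rises 94 were lower at 400 than at 100 mM at an unadjusted p under 0.05. That is above the 40 to 67 of simulations with no change. Of the 43 falls 37 were higher, within the simulated 28 to 37. The simulated clusters were not matched to the called ones in abundance or spread, so these ranges do not decide it. Between both salt levels 0 clusters passed edgeR's test, with 3992 at an unadjusted p under 0.05 and 1363 called by DESeq2. Salt was raised stepwise so that the levels were reached together, so plants at 400 mM may have been in salt for longer. Salt level and time in salt cannot be told apart here.

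Regrouping 6 libraries as 3 against 3 gives 10 splits, too few for a share under 0.05. For 100 mM against 0 mM the real split gave 284 calls and the highest other split 1, so 1 of 10 splits gave as many. For 400 mM against 0 mM and 400 mM against 100 mM the real splits gave 0 calls and the highest other 1, so 10 of 10 gave as many. At an unadjusted p under 0.05 the real splits gave 8768, 7406 and 3992 clusters for 100 against 0, 400 against 0 and 400 against 100 mM, and the highest other splits 3586, 3582 and 3727.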
